A study of Mus musculus with 12 samples.

How the data were processed

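The series holds 12 RNA-seq libraries of mouse ZHBTc4 embryonic stem cells in 6 groups of 2 replicates: WT and Phf6 KO cells, each untreated, with doxycycline or with retinoic acid. Groups were taken from the sample titles. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. They also name no batch, and do not say how many lines of each genotype were sequenced. Per the labels' protocols, RNA of the retinoic acid samples went through another extraction kit than that of the other samples.

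Reads were aligned with STAR 2.5.3a and quantified with RSEM 1.3.0 on mm10, and DESeq2 1.18.1 was used, per the submitters' processing notes. The annotation release and the strand setting are not given in the sources used here. Per the file headers, the authors deposited 1 RSEM gene table per library with the expected counts, TPM and effective length of each gene. Expected counts are estimates that divide reads shared by several genes, and 9.5% to 11.6% of the genes per library had values that were not whole. The deposited TPM values were not used, and the deposited effective lengths entered only 1 alternative. Because RSEM divides shared reads by model, values of near-identical copies (Zscan4, Tcstv, Usp17l, Rhox and Xlr genes) are uncertain. With no strand setting given, Airn, Kcnq1ot1 and Hoxb5os, which overlap genes on the other strand, are uncertain as well.

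Gene identifiers were matched to GENCODE release M21 (GRCm38) for coordinates: 53274 of 53379 were found. Expected counts were rounded to whole numbers. Total counts were 15799569 to 21442034 per library, mitochondrial genes took 1.19% to 1.64%, and 3 counts in a library, the limit that a count of 0 allows, equal 0.14 to 0.19 CPM. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. For a group with no read, a fold is given as a lower bound against a floor of 3 counts per library, averaged over the 2 libraries of the group. The replicates of a group differed by more than sampling noise (chi-square per degree of freedom 1.92 to 6.17), so no library was taken for a copy of another, and their log2 CPM correlated at 0.99.

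Genes were filtered with edgeR's filterByExpr by group (minimum count 10), which kept 17884 genes. Libraries were scaled by TMM (factors 0.9 to 1.16). All 12 libraries entered 1 edgeR quasi-likelihood fit (edgeR 4.0.16, limma 3.58.1, R 4.3.3; glmQLFit with robust, glmQLFTest) with 1 term per group and 6 residual degrees of freedom. The typical coefficient of variation between replicates was 4.4%. The 9 contrasts tested were KO against WT in each of 3 conditions, each treatment against untreated in each line, and the difference between KO and WT in each treatment response. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. CPM values use the rounded counts over TMM-scaled library sizes.

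The 21 gene lists cover pluripotency, formative epiblast, trophectoderm, placental differentiation, primitive endoderm, primitive streak and mesoderm, neural, retinoic acid response, Hox clusters, feeder fibroblast, 2-cell-embryo, ribosome biogenesis, NuRD complex, histone H2B ubiquitination, p53 targets, hypoxia and glycolysis, interferon-stimulated, imprinted, germline, Y-linked and epithelial junction genes. They hold 473 different genes, of which 428 were tested. Each list was tested with camera in each contrast at a preset correlation of 0.01, and its adjusted p is over all 189 such tests. Of the 84 tests past the threshold, 51 held with an estimated correlation. Adjusted over the list alone, the numbers of members called higher or lower moved by at most 4, and 299 of 378 such numbers did not move. Among the 84 tests, median, mean and direction of the test differed in sign for 3, given with their values in the results.

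Named genes were Phf6 and Pou5f1 throughout; per contrast the 6 genes with the largest positive and the 6 with the largest negative log2 change among called genes with at least 5 CPM in the higher group, no overlap of the libraries of the 2 groups (not asked of the differences between responses) and no predicted or clone-based symbol; the members of the lists; and genes fixed in advance, among them Cdx2, Eomes, Elf5, Gata3, Hand1 and Krt8 for doxycycline and Rarb, Cyp26a1, Gata6, Nanog and Sox2 for retinoic acid. Groups, tests, lists, this rule and the other settings tried were fixed before the data were examined.

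The fit was tested on simulated data first. Counts for all 12 libraries were drawn from each gene's mean over all libraries, its dispersion and the library sizes, with 200 genes changed by known folds between KO and WT in doxycycline. Of 17014 genes tested there, 100% of those changed 4-fold were recovered, 80.9% at 2-fold, 53.1% at 1.5-fold and 44% at 1.25-fold, and 9 of 16789 unchanged genes were called. For the difference between KO and WT in the doxycycline response, 93.9% were recovered at 4-fold, 68.1% at 2-fold, 44.9% at 1.5-fold and 22% at 1.25-fold. A list of 30 genes lowered by 0.5 on the log2 scale was called and 0 of 20 unchanged lists. Genes were drawn independently and few were changed. The simulation therefore tests neither the scaling under broad changes nor the effect of correlation between genes on the list tests.

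Alternatives were DESeq2 size factors or upper-quartile factors in place of TMM, no filter or a stricter filter (1 CPM in 2 libraries), RSEM effective lengths as offsets, the replicate number as a block, DESeq2 1.42.0 in place of edgeR, a fit on only the groups compared, leaving out each library in turn, and for lists an estimated correlation and fry. Fits without chromosome 1 genes, and with a crossed block, were added after seeing the data.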

Results

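RNA of mouse ZHBTc4 embryonic stem cells was sequenced. In this line the native alleles of Pou5f1, the gene of the pluripotency factor Oct4, are disrupted, and Oct4 comes from a transgene that doxycycline switches off. Loss of Oct4 directs embryonic stem cells toward trophectoderm, the lineage that builds the placenta. Wild type (WT) cells were compared with Phf6 knockout (KO) cells, each left untreated, treated with doxycycline for 2 days (0.5 µg/ml in the sample labels, 0.5 mg/ml in their protocol text), or treated with all-trans retinoic acid for 4 days in medium without leukemia inhibitory factor. The series title names trophectodermal genes as the target of the chromatin-binding protein PHF6. Each of the 6 groups had 2 libraries, and libraries held between 15799569 and 21442034 counts. Values are mean CPM (counts scaled to library size by edgeR) ± SD over the 2 libraries of a group, and fold changes are log2 values ± SE. This SE is the log2 change divided by the square root of the F statistic of the edgeR test. For a gene with few reads in 1 group it can be smaller than the counting error. The first principal component held 47.9% of the variance and set the retinoic acid libraries apart. The second held 33.4% and set the doxycycline libraries apart, and the third, with 7.2%, separated KO from WT in every condition.

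The targeted gene was examined first. Phf6 (ENSMUSG00000025626.16, chromosome X, 52912266 to 52956943, GRCm38) encodes a nuclear protein with PHD-type zinc fingers. It stood at 41.5 ± 1.83 CPM in untreated WT cells and at 5.49 ± 1.43 in untreated KO cells. With doxycycline the levels were 32.5 ± 3.72 and 7.79 ± 0.568 CPM, and with retinoic acid 40.5 ± 0.295 and 5.93 ± 0.0466 CPM. The KO to WT change was -2.91 ± 0.12, -2.06 ± 0.11 and -2.77 ± 0.11 in the 3 conditions, with edgeR adjusted p-values of 2.7e-16, 3.6e-14 and 3.1e-17. Gene totals do not show which exons the remaining reads came from.

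Pou5f1 (ENSMUSG00000024406.16, chromosome 17, 35506018 to 35510772) followed doxycycline in both lines. It fell from 1022 ± 13 to 40.2 ± 8.68 CPM in WT and from 1194 ± 2.39 to 13.7 ± 0.883 CPM in KO. In doxycycline the KO level was below the WT level by -1.57 ± 0.13 (adjusted p = 1.9e-06). With retinoic acid Pou5f1 stayed at 1027 ± 76.5 CPM in WT and 983 ± 9.59 CPM in KO, and the KO to WT test was not passed there (adjusted p = 0.61) or in untreated cells (adjusted p = 0.075).

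**Figure D1:**
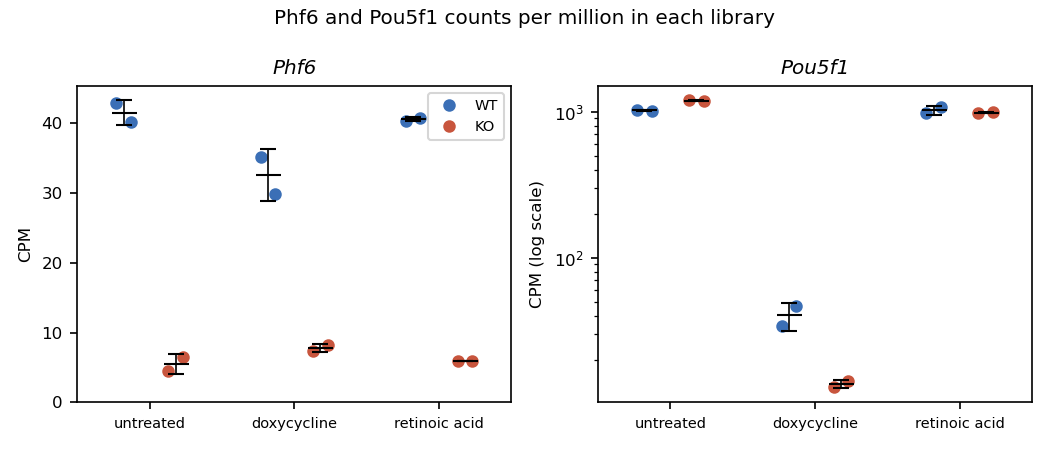
CPM (vertical axis, linear for Phf6 and log scale for Pou5f1) in the 2 libraries of each group (points, WT blue, KO red), with the group mean and SD (bars). Phf6 lay at 5.49 to 7.79 CPM in the KO groups and at 32.5 to 41.5 CPM in the WT groups, and Pou5f1 dropped to 40.2 (WT) and 13.7 (KO) CPM with doxycycline.

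Doxycycline in WT cells turned off the stem cell program and turned on trophectoderm genes. Of the 28 pluripotency genes tested, 25 fell and 1 rose, with a median of -3.33 (adjusted p = 5.9e-79). Nanog, a core pluripotency transcription factor, fell from 946 ± 24 to 204 ± 6.27 CPM, and Esrrb, a nuclear receptor of self-renewing cells, changed by -5.92. Fgf4, a growth factor made by stem cells, fell from 218 ± 0.656 to 0.405 ± 0.284 CPM. Of 30 trophectoderm genes, 20 rose and 6 fell (adjusted p = 5.1e-29). Cdx2, the homeobox regulator of trophectoderm, rose from 1.09 ± 0.127 to 121 ± 5.25 CPM, and Gata3, a GATA factor of the same lineage, from 1.97 ± 0.122 to 86 ± 3.77 CPM. Hand1, needed for trophoblast giant cells, changed by 5.19 ± 0.13, and the keratin gene Krt8 by 4.94 ± 0.092. Eomes, another trophectoderm regulator, did not pass (3.42 and 3.62 CPM), and Elf5 had 0 to 4 counts per library and was not tested.

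Other groups moved with them. In the placental list 12 of 16 genes rose (list adjusted p = 4.4e-09), among them Ascl2, a regulator of spongiotrophoblast, from 6.19 to 71.9 CPM. The other 13 of its 29 genes, including Tpbpa, Prl3d1, Prl3b1 and Synb, markers of differentiated placental cells, had 0 to 4 counts per library and were not tested. Of 30 imprinted genes, 21 rose (list adjusted p = 8.4e-19), and Igf2, a fetal growth factor, went from 19 ± 0.167 to 2609 ± 39.5 CPM. Ribosome biogenesis genes fell (26 of 30, median -0.54, adjusted p = 6.7e-07), as did 12 of 17 formative epiblast genes (adjusted p = 1.5e-17). By fold and the naming rule, large risers included Dkk1, a secreted Wnt antagonist, from 0.0623 to 103 CPM, Slc6a14, an amino acid transporter, from 0.0588 to 18.6 CPM, and the homeobox gene Hoxc9, from 0.0623 to 9.35 CPM. Aoah, a lipase that inactivates endotoxin, was at least 83.7-fold lower and the homeobox gene Nkx6-3 at least 73.3-fold lower, since neither had a read in doxycycline-treated WT cells. Foxd3, a stem cell forkhead factor, changed by -7.66 ± 0.18.

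The KO cells responded to doxycycline with the same main groups. Pluripotency genes fell (26 of 28, median -4.38, adjusted p = 9.6e-97) and trophectoderm genes rose (22 of 30, 4 lower, adjusted p = 1.1e-14). Cdx2 reached 15.6 ± 0.608 CPM from 0.472 ± 0.238, Gata3 51.3 ± 2.95 from 0.653 ± 0.108, Hand1 50.7 ± 2.94 from 2.49 ± 0.525 and Krt8 760 ± 53.6 from 24.5 ± 3.69. Csf1, a macrophage growth factor, rose by 8.17 ± 0.13, Zfp36l3, an RNA-binding protein of the placenta, by 7.01 ± 0.13 and Dkk1 to 92.8 ± 2.5 CPM. Tcl1, an activator of Akt signaling in stem cells, changed by -8.88 ± 0.14, and Nr0b1, a nuclear receptor of the pluripotency network, by -8.54 ± 0.11. The placental (9 higher, 3 lower of 16, adjusted p = 0.0013), imprinted (21 higher, 3 lower of 30, adjusted p = 1.1e-10), formative epiblast (4 higher, 12 lower of 17, adjusted p = 2.3e-18) and ribosome biogenesis lists (28 of 30 lower, adjusted p = 2.6e-08) were also called.

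Doxycycline changed 11273 of 17884 genes in WT (5681 higher, 5592 lower) and 11146 in KO (5574 higher, 5572 lower). Of these, 4447 were higher and 4411 lower in both lines, where independent lists would share 1770.6 and 1742.3. With upper-quartile factors the calls were 4817 higher and 6558 lower in WT and 5175 and 6038 in KO. The lines share no library, so the overlap of the main calls does not come from a common control. Several further calls in doxycycline were lost with an estimated correlation between genes. These were the primitive endoderm list (10 of 23 higher in WT, adjusted p = 0.19 with an estimated correlation, and 10 in KO, 0.18), the epithelial junction list (13 of 22 higher in WT, 0.16, and 14 in KO, 0.19) and the hypoxia and glycolysis list (12 of 24 lower in WT, adjusted p = 0.61 with an estimated correlation, and 18 in KO, 0.45). The neural list in WT had 5 of 16 genes higher and 8 lower (adjusted p = 0.14 with an estimated correlation), with a median of -0.34 and a mean of 0.24.

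Untreated KO cells already differed from WT cells. Xcr1, a chemokine receptor, was at 0.275 ± 0.139 CPM in WT and 6.68 ± 0.425 in KO, a change of 4.58 ± 0.31 (adjusted p = 4.7e-12). H19, an imprinted noncoding RNA (ENSMUSG00000000031.16, chromosome 7, 142575529 to 142578143), was at 22.7 ± 1.3 CPM in WT and 0.601 ± 0.419 in KO, a change of -5.24 ± 0.18 (adjusted p = 2.4e-18). Islr2, a leucine-rich repeat protein of neurons, rose by 1.87 ± 0.089, Prkcb, a protein kinase C, by 2.18 ± 0.22, Anxa8, an annexin, by 2.38 ± 0.21 and Olfm2, an olfactomedin, by 2.02 ± 0.18. Meis2, a homeobox gene, changed by -3.67 ± 0.29, and the X-linked genes Pnma5, Fmr1nb, Efhc2 and Xlr3a by -3.10, -3.29, -3.95 and -5.18. Xlr3a has near-identical copies, so its reads could be split between them. For each of these genes both KO libraries lay on the same side of both WT libraries, which the naming rule required.

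Of 30 trophectoderm genes, 15 were lower and 2 higher in untreated KO cells, with a median of -0.40 (adjusted p = 6.9e-05, and adjusted p = 0.13 with an estimated correlation). The count adjusted over the list alone was 16 lower and 2 higher. Tfap2a and Gata3, transcription factors of early trophectoderm, changed by -2.63 and -1.58, and Esx1, a placental homeobox gene, by -1.62; the call of Gata3 was lost with effective-length offsets. Of 22 p53 targets, 17 rose and 1 fell, also when adjusted over the list alone, with a median of 0.35 (adjusted p = 4.5e-08, and adjusted p = 0.06 with an estimated correlation). Plk2, a stress-induced kinase, rose by 1.26 and Bbc3, a proapoptotic gene, by 1.07. Of 24 hypoxia and glycolysis genes, 10 rose and 1 fell, and adjusted over the list alone 12 and 2 (adjusted p = 0.00042, and adjusted p = 0.5 with an estimated correlation). The 2-cell-embryo list had 7 of 17 genes lower (adjusted p = 0.14 with an estimated correlation), the ribosome biogenesis list 11 of 30 (0.14, and 0.072 without chromosome 1 genes, which include 4 of the 11), the germline list 7 of 19 (0.16) and the epithelial junction list 11 of 22 (0.21).

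Pluripotency genes went both ways in untreated cells, with 8 of 28 higher and 10 lower (adjusted p = 0.38). Adjusted over the list alone these were 12 and 10. Klf4, a pluripotency factor, rose from 283 to 499 CPM, while Dppa3, a maternal factor, fell from 2.1 to 0.535 CPM. The lists of complexes tied to the question did not pass: 7 of 20 genes of histone H2B ubiquitination changed (4 higher, 3 lower, adjusted p = 0.67) and 7 of 15 genes of the NuRD remodeling complex (1 higher, 6 lower, adjusted p = 0.14). In the fit without chromosome 1 genes, added after seeing the data, the NuRD list passed (camera adjusted p = 0.028, and 0.022 with doxycycline). None of its tested genes lies on that chromosome, but camera compares a list with the other genes tested, and these changed. In the main fit with an estimated correlation the NuRD list did not pass (camera adjusted p = 0.23, and 0.16 with doxycycline). Formative epiblast (7 higher, 4 lower of 17, adjusted p = 0.056), primitive streak and mesoderm (2 of 14), neural (4 higher, 5 lower of 16), retinoic acid response (3 higher, 2 lower of 20), Hox (1 higher, 3 lower of 38), interferon (2 higher, 3 lower of 15), primitive endoderm (5 higher, 5 lower of 23), placental (2 higher, 1 lower of 16), feeder fibroblast (5 higher, 3 lower of 17) and imprinted genes (6 higher, 11 lower of 30) did not pass as lists either. In all, 5369 of 17884 genes differed (2713 higher, 2656 lower), 871 of them by at least 2-fold; with the DESeq2 test 1487 were higher and 1943 lower.

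Genes of chromosome 1 were lower in KO cells along its whole length. Among 840 chromosome 1 genes with a mean of at least 1 CPM, the median change was -0.47 untreated, -0.48 with doxycycline and -0.47 with retinoic acid, a fold of 0.72. In the 3 conditions 85.1%, 84.5% and 88.0% of them lay below 0, against 43.3%, 46.2% and 47.6% on the other autosomes. Bins of 20 Mb had medians from -0.54 to -0.37, and no other autosome had a median outside -0.10 to 0.10. Chromosome 1 held 6.1% of the tested genes and 21.2%, 16.6% and 17.7% of those called lower. Y-linked genes were higher in KO cells: all 4 tested rose untreated (median 1.20, adjusted p = 6.5e-10), and 3 rose with each treatment. Ddx3y, an RNA helicase gene, was at 21.7 CPM in untreated WT and 59.3 in untreated KO cells.

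**Figure D2:**
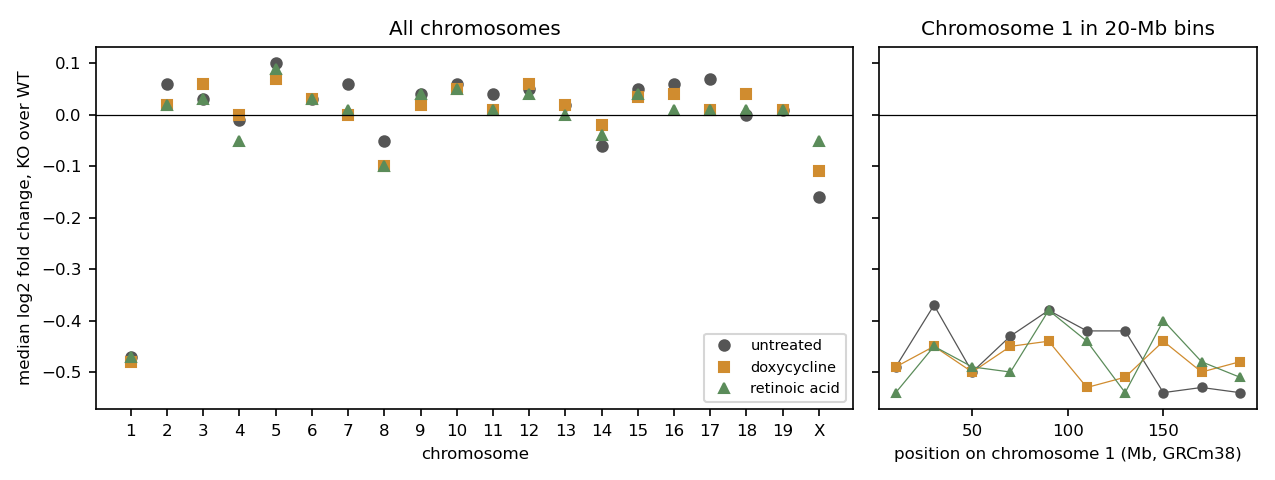
Median log2 fold change of KO over WT (vertical axis) for genes with a mean of at least 1 CPM, per chromosome (left) and in bins along chromosome 1 (right), in untreated, doxycycline and retinoic acid libraries (symbols). Chromosome 1 lay at -0.48 to -0.47 in all 3 conditions, with bins from -0.54 to -0.37, while the other autosomes stayed within 0.10 of 0.

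Without chromosome 1 genes, an alternative chosen after seeing the data, 4640 genes differed untreated, 5965 with doxycycline and 6222 with retinoic acid. List members on chromosome 1 that were lower in all 3 conditions included Tfcp2l1 and Nr5a2 (pluripotency) and Ncl, Nop58, Wdr12 and Rrs1 (ribosome biogenesis).

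With doxycycline, KO cells reached lower levels of trophectoderm genes than WT cells. Cdx2 (ENSMUSG00000029646.3, chromosome 5, 147300805 to 147307270) was at 121 ± 5.25 CPM in WT and 15.6 ± 0.608 in KO, a change of -2.95 ± 0.09 (adjusted p = 3.1e-20). Tfap2c, an AP-2 factor of trophoblast, changed by -2.39, Gata2 by -1.49, Gata3 by -0.74, Hand1 by -0.69 and Krt8 by -0.52. Of the 30 trophectoderm genes, 22 were lower and 1 higher, over all genes and adjusted over the list alone, with a median of -0.78 (adjusted p = 4.9e-33). The call held with an estimated correlation (adjusted p = 0.0052). The homeobox genes Rhox9 and Rhox6 changed by -3.08 and -2.57; they are similar members of 1 cluster, and their reads could be shared. Itga7, an integrin, was the member that rose (4.645 and 10.53 CPM), and Eomes did not pass (adjusted p = 0.74).

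**Figure D3:**
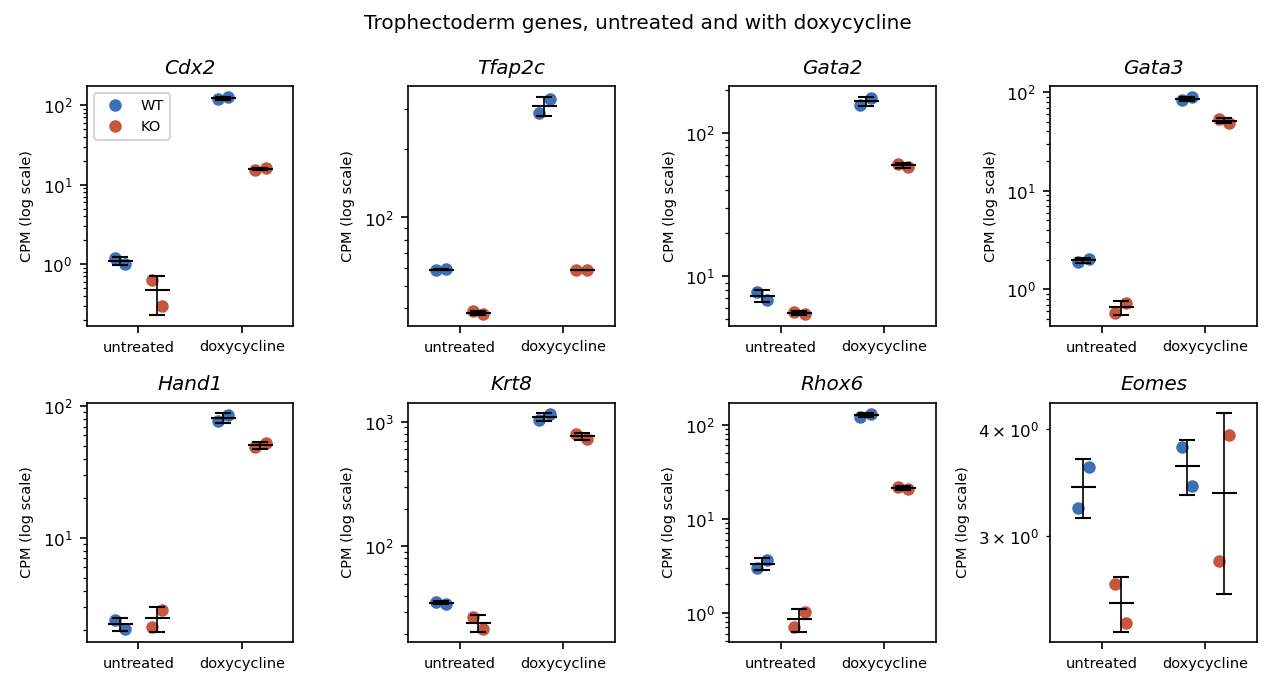
CPM (vertical axes, log scale) of 8 trophectoderm genes in the 2 libraries of untreated and doxycycline-treated WT (blue) and KO (red) cells, with group means and SD (bars). With doxycycline Cdx2 reached 121 CPM in WT and 15.6 CPM in KO, and Krt8 1089 and 760 CPM.

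Placental genes were lower as well (8 of 16, 1 higher, median -0.76, adjusted p = 9e-10). Ascl2 was at 71.9 CPM in WT and 11.3 in KO, Phlda2, a regulator of placental growth, at 260 and 54.6, and Peg10, a retrotransposon-derived gene needed for the placenta, at 14720 and 6967. Pluripotency genes were lower too (21 of 28, 4 higher, median -0.76, adjusted p = 1.2e-10; 22 lower adjusted over the list alone). Nanog stood at 204 ± 6.27 CPM in WT and 112 ± 1.9 in KO, while Sox2, a neural and pluripotency factor, was higher by 0.86. H19 had the largest fold change by the naming rule (1631 ± 53.5 against 10.3 ± 0.357 CPM), and among imprinted genes 15 of 30 were lower and 7 higher (median -0.34, or -0.52 without chromosome 1 genes, adjusted p = 6.1e-13). Other large decreases were in Stra6l, a receptor of retinol-binding protein (-4.91), Adh1, an alcohol dehydrogenase (-4.59), Klk7, a kallikrein protease (-3.75) and Myl3, a myosin light chain (-3.89).

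Neural and fibroblast genes were higher in KO cells with doxycycline. Of 16 neural genes, 7 rose and 3 fell (median 0.65, adjusted p = 3.7e-05), with Stmn2, a tubulin-binding protein of growing axons, at 26.8 CPM in WT and 104 in KO, and Nes, the progenitor filament nestin, at 56.2 and 125. Of 17 genes used as markers of feeder fibroblasts, 10 rose and 0 fell (median 0.82, adjusted p = 2.7e-05), among them Col1a1, a fibrillar collagen, at 8.47 and 20.1 CPM. The early passages of the line were grown on feeder cells, per the labels. Large fold increases by the naming rule were in Xcr1 (0.305 to 19.09 CPM), Vgf, a neuropeptide precursor (3.42), Cdh6, a cadherin (2.78), Trh, the thyrotropin-releasing hormone (2.56), Crmp1, a semaphorin signal mediator (2.52) and Dchs1, a protocadherin (2.51). Calls lost with an estimated correlation were p53 targets (13 of 22 higher, adjusted p = 0.1 with an estimated correlation), ribosome biogenesis (15 of 30 lower, 0.1) and epithelial junctions (15 of 22 lower, 4 higher, 0.14). In total 6616 genes differed (3197 higher, 3419 lower), 1418 by at least 2-fold. The share called higher was 48.3%, and 60.6% when libraries were scaled by upper-quartile factors.

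The response to doxycycline itself differed between the lines for 3425 genes (1630 more positive and 1795 more negative in KO). With upper-quartile factors 61.9% of the calls were more positive in KO, against 47.6% with the main scaling. Pluripotency genes were turned down further in KO (17 of 28 more negative, 4 more positive, median -0.57, adjusted p = 7.7e-14), Pou5f1 by -1.80 ± 0.16 and Tdgf1, a Nodal coreceptor, by -1.97. Trophectoderm genes as a list showed a smaller rise (13 of 30 more negative, 4 more positive, median -0.57, adjusted p = 0.0052), a call lost with an estimated correlation (adjusted p = 0.24 with an estimated correlation). Adjusted over the list alone 15 were more negative and 7 more positive. Cdx2 (-1.75 ± 0.5), Tfap2c (-1.76), Gata2 (-1.08) and Hand1 (-0.85 ± 0.25) rose less in KO. The calls of Gata2 and Hand1 were lost with effective-length offsets, that of Cdx2 without 1 untreated KO library, and that of Hand1 without either of 2 untreated libraries. Gata3 (0.83 ± 0.37, adjusted p = 0.12) and Krt8 (0.02 ± 0.13, adjusted p = 0.97) did not pass, each being lower in KO before and after treatment.

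Neural genes (6 more positive, 2 more negative of 16, median 0.78, adjusted p = 2e-05), fibroblast markers (10 of 17 more positive, median 0.92, adjusted p = 0.00055) and placental genes (4 of 16 more negative, median -0.91, adjusted p = 2.6e-08) also responded differently. Gap43, a growth cone protein, fell in WT (47.9 to 28 CPM) and rose in KO (26 to 65.2 CPM), a difference of 2.10. The imprinted list was called with 10 of 30 genes more negative and 6 more positive (adjusted p = 9.6e-06), though its median was -0.27 and its mean 0.02. Hypoxia and glycolysis genes had 9 of 24 more negative and 4 more positive (adjusted p = 0.57 with an estimated correlation). Among single genes, Pth1r, the parathyroid hormone receptor, rose from 1.23 to 41.25 CPM in WT and from 1.96 to 4.03 in KO. Nog, a BMP antagonist, rose from 0.155 to 6.42 CPM in KO and from 0.7005 to 2.25 in WT.

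Retinoic acid in WT cells raised its known targets, Hox genes and primitive endoderm genes. Of 20 retinoic acid response genes, 17 rose and 3 fell (median 4.49, adjusted p = 8.5e-29). Cyp26a1, which degrades retinoic acid, went from 0.0917 to 125 CPM, and Rarb, a retinoic acid receptor, changed by 5.99 ± 0.22. Of 38 Hox genes, 36 rose (adjusted p = 1.4e-18); Hoxb1, Hoxb2 and Hoxb3 had no read in untreated cells and were at least 205-fold, 139-fold and 108-fold higher. Of 23 genes of primitive endoderm, the extraembryonic layer that lines the yolk sac, 22 rose and 1 fell (adjusted p = 6.3e-44), with a median of 4.72, or 3.87 with genes at 0 set to their bound. Gata6, its master regulator, rose from 0.552 to 56.4 CPM, and Lama1, a laminin of its basement membrane, from 95.2 to 1930 CPM.

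Pluripotency genes fell (26 of 28, median -1.17, adjusted p = 1.6e-32), with Nanog at 422 ± 12.2 and Sox2 at 115 ± 2.42 CPM. All 30 ribosome biogenesis genes fell (median -1.37, adjusted p = 1.7e-28), and all 17 genes of the 2-cell-embryo list rose (median 4.91, adjusted p = 3.6e-16), with the Zscan4 genes from 0.484 to 3.64 CPM untreated up to 17.2 to 168 CPM. The Zscan4, Tcstv and Usp17l members of that list are near-identical copies, and how reads were divided among them is uncertain. Imprinted genes rose (25 of 30, adjusted p = 1.9e-12). Large fold decreases by the naming rule were in Nkx6-3, Pou4f2, a POU homeobox gene (-7.26), Khdc3, an oocyte and early embryo protein (-5.85), and Platr10, a noncoding RNA of stem cells (-5.04).

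KO cells gave the same groups with retinoic acid: pluripotency (26 of 28 lower, median -2.47, adjusted p = 1.3e-48), primitive endoderm (22 of 23 higher, adjusted p = 1.2e-58), retinoic acid response (18 of 20 higher, adjusted p = 1.4e-24), Hox (35 of 38 higher, adjusted p = 2.4e-15), the 2-cell-embryo list (17 of 17 higher, adjusted p = 8e-10), imprinted (24 of 30 higher, adjusted p = 5.6e-08), formative epiblast (12 of 17 lower, adjusted p = 1.5e-07) and ribosome biogenesis (30 of 30 lower, adjusted p = 1.3e-28). Hoxa5 and Hoxb4, with no read in untreated KO cells, were at least 408-fold and 302-fold higher. Otx2, an epiblast homeobox gene, changed by -7.58 ± 0.22, Tdgf1 by -7.56 ± 0.21, and Spry4, a feedback inhibitor of FGF signaling, by -6.47 ± 0.075. Calls lost with an estimated correlation were trophectoderm (19 of 30 higher in each line, adjusted p = 0.14 with an estimated correlation in both), feeder fibroblast (14 of 17 in WT, 0.079, and 13 in KO, 0.15), germline (14 of 19 in each, 0.14 in WT and 0.13 in KO), and in WT formative epiblast (12 of 17 lower, 0.11), placental (10 of 16 higher, 0.079) and primitive streak and mesoderm (11 of 14 higher, 0.14).

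Retinoic acid changed 13215 genes in WT (7332 higher, 5883 lower) and 13504 in KO (7320 higher, 6184 lower). Of these 6324 were higher and 5144 lower in both lines, where independent lists would share 3001 and 2034.2. The median over all genes was 0.12 in WT and 0.103 in KO, so a gene's change here is read against that shift. The retinoic acid libraries also differed from the others in the RNA extraction kit named in the labels and in the medium, so the treatment cannot be told apart from these in the comparison with untreated cells; the KO to WT comparison was made within 1 protocol.

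With retinoic acid, KO cells lost more of the pluripotency program and gained more primitive endoderm expression than WT cells. Nanog was at 422 ± 12.2 CPM in WT and 75.1 ± 2.75 in KO, a change of -2.49 ± 0.053 (adjusted p = 1.6e-23). Of the 28 pluripotency genes 22 were lower and 3 higher, over all genes and adjusted over the list alone (median -0.93, adjusted p = 1.8e-40). Esrrb changed by -2.19, Klf2, a naive-state factor, by -1.84 and Zfp42, a marker of undifferentiated cells, by -1.63, while Pou5f1 did not pass. Of 23 primitive endoderm genes 21 were higher and 0 lower, also when adjusted over the list alone (median 0.90, adjusted p = 5.4e-38). Cubn, an endocytic receptor of visceral endoderm, was at 355 CPM in WT and 1440 in KO, Dab2, its adaptor protein, at 166 and 470, and Ttr, the thyroid hormone carrier of visceral endoderm, at 1.98 and 10.1. Gata6 and Gata4 rose by 0.80 and 0.90. Both calls held with an estimated correlation (adjusted p = 0.0019 and 0.0033).

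**Figure D4:**
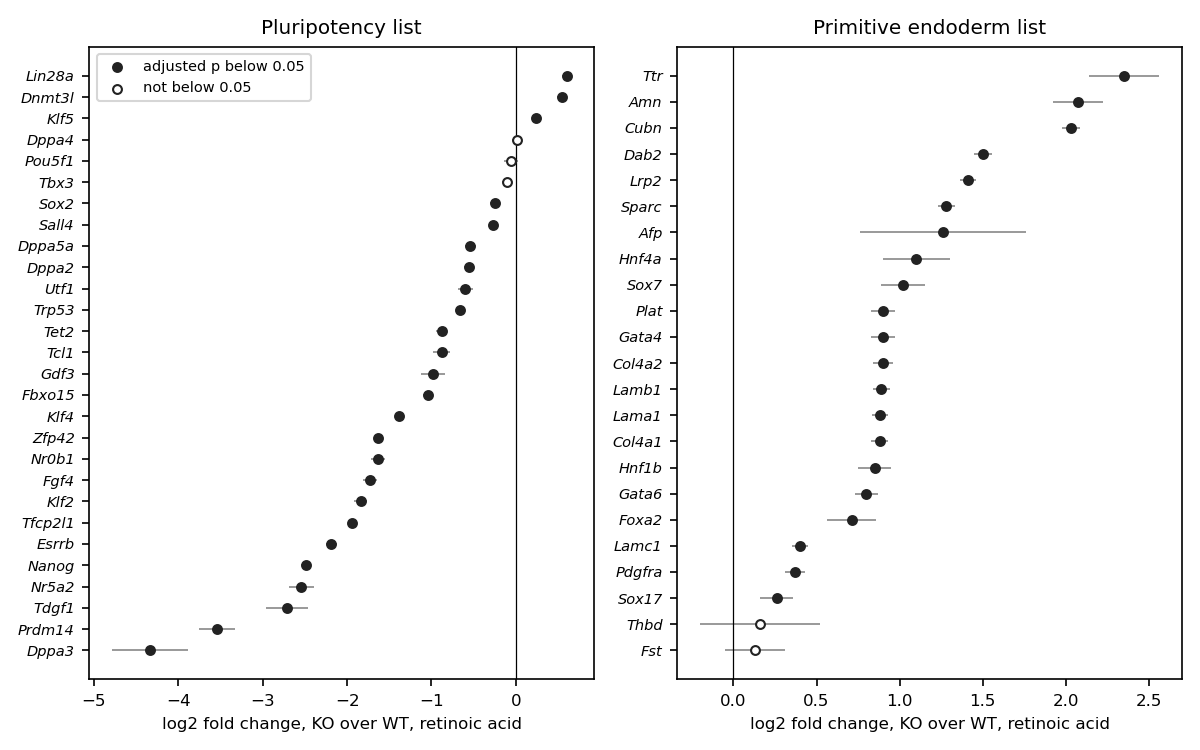
Log2 fold change of KO over WT with retinoic acid (horizontal axes, bars ± SE) for the tested genes of the pluripotency and primitive endoderm lists; filled points passed adjusted p of 0.05. Of 28 pluripotency genes 22 lay below 0 and passed, and of 23 primitive endoderm genes 21 lay above 0 and passed.

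Formative epiblast genes were lower (9 of 17, 3 higher, median -0.73, adjusted p = 2.5e-08; without chromosome 1 genes -0.43 and 2.5e-05), among them the Nodal antagonists Lefty2 (-2.99) and Lefty1 (-2.38), both on chromosome 1, and Otx2 (1.017 and 0.1486 CPM). The 2-cell-embryo list (12 of 17 lower, adjusted p = 3.1e-08), ribosome biogenesis (25 of 30 lower, median -0.24, adjusted p = 3.1e-08) and imprinted genes (14 of 30 lower, 7 higher, adjusted p = 0.00061) were called too. Calls lost with an estimated correlation were hypoxia and glycolysis (14 of 24 higher, adjusted p = 0.51 with an estimated correlation), p53 targets (10 of 22 lower, 2 higher, 0.41) and epithelial junctions (10 of 22 lower, 5 higher, 0.14), the last with a median of 0.03 against a mean of -0.27. Targets of retinoic acid split evenly (7 of 20 higher, 7 lower, adjusted p = 0.67): Cyp26a1 (0.63) and Rarb (0.62) rose, and Cdx1, a caudal homeobox gene, changed by -2.67. The call of Rarb was lost with effective-length offsets, and that of p53 targets without chromosome 1 genes (adjusted p = 0.13). Hox genes (10 higher, 9 lower of 38, adjusted p = 0.76), trophectoderm (7 higher, 14 lower of 30, adjusted p = 0.11), placental (2 higher, 7 lower of 16, adjusted p = 0.089, and 0.045 without chromosome 1 genes) and neural genes (6 of 16 higher, adjusted p = 0.093) did not pass as lists.

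Genes with large increases by the naming rule with retinoic acid were Xcr1 (0.091 and 16.2 CPM), Ugt2b34, a glucuronosyltransferase (2.66), Smoc2, a matricellular protein (2.92), and B3gat1, a glucuronyltransferase of the nervous system (2.27). H19 (-6.16), Npr3, the natriuretic peptide clearance receptor (-4.38), Plagl1, an imprinted zinc finger gene (-4.22), and the chromosome 1 genes Prdm14, a regulator of naive pluripotency (-3.54), Msc (-3.55) and Inhbb, an activin subunit (-3.43), were lower. In all, 6935 genes differed (3357 higher, 3578 lower), 1240 by at least 2-fold.

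The response to retinoic acid differed between the lines for 3155 genes (1308 more positive and 1847 more negative in KO). The share more positive, 41.5%, was 48.4% with DESeq2 size factors and 50.7% with the DESeq2 test, so the excess of negative differences depends on the method. Nanog fell further in KO, by -2.16 ± 0.071 beyond its fall in WT, and Sox2 by -0.63 ± 0.074. Pluripotency genes (21 of 28 more negative, 2 more positive, median -1.14, adjusted p = 6e-56; 23 more negative adjusted over the list alone) and formative epiblast genes (10 of 17 more negative, 1 more positive, adjusted p = 1.1e-18) were turned down further. Primitive endoderm genes rose further (12 of 23 more positive, 1 more negative, median 0.99, adjusted p = 5.5e-17; 15 and 2 adjusted over the list alone), with Dab2 at 2.92 and Sparc, a matrix protein of parietal endoderm, at 1.88. Dab2 was also lower in untreated KO than in untreated WT cells, so its difference includes that gap. Of 22 p53 targets, 17 were more negative and 2 more positive (median -0.62, adjusted p = 4.9e-15), with the kinase gene Plk2 at -1.24. The KO to WT median of these targets was 0.35 untreated and -0.12 with retinoic acid. Plk2 too was higher in untreated KO cells, so these differences include the untreated gap. Trophectoderm genes had 12 of 30 more positive and 6 more negative (adjusted p = 0.0053, and adjusted p = 0.24 with an estimated correlation), and ribosome biogenesis genes 8 of 30 more negative (adjusted p = 0.12 with an estimated correlation). Rarb, Cyp26a1 and Gata6 did not pass.

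**Figure D5:**
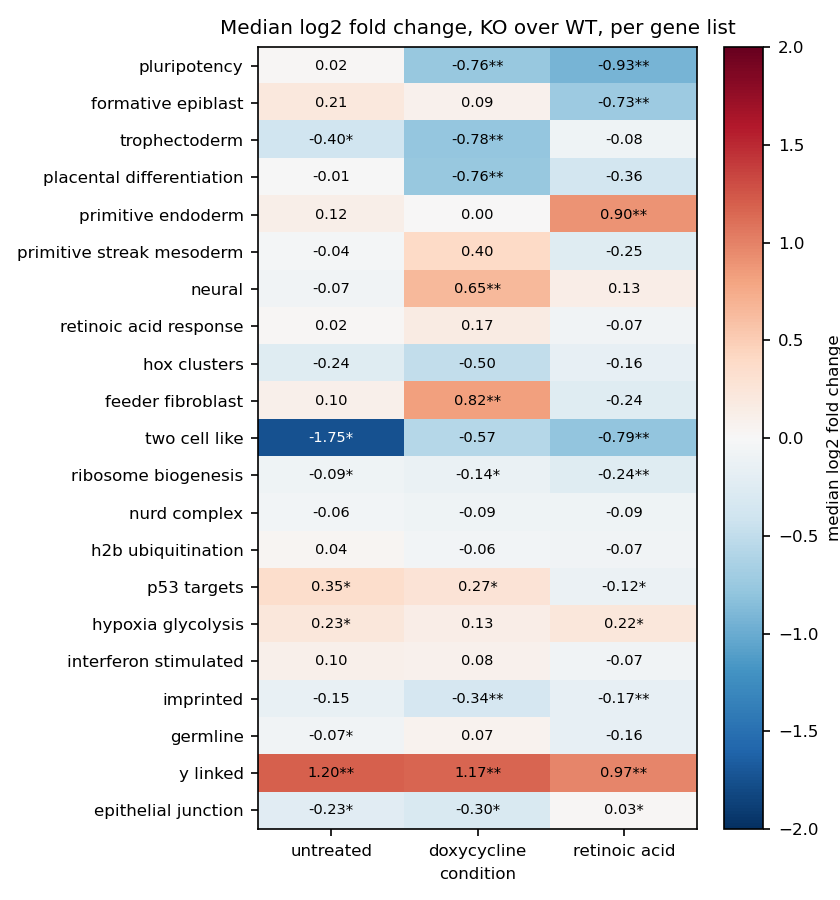
Median log2 fold change of KO over WT (color and printed value) for the 21 gene lists (vertical axis) in 3 conditions (horizontal axis). A star marks a list past adjusted p of 0.05 with the preset correlation, and a double star a list that also passed with an estimated correlation, such as trophectoderm with doxycycline (-0.78) and primitive endoderm with retinoic acid (0.90).

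Across all 3 conditions 719 genes were higher and 1053 lower in KO each time, where 91 and 101.6 would be shared by independent lists. The 3 comparisons share no library, but any fixed difference between the WT and KO cells, such as that of chromosome 1, recurs in each. The share higher was 40.6%, and between 33.4% and 48.2% in other fits of all the libraries, the latter with upper-quartile factors. Of the 719 and 1053 genes, 55 and 71 differed by at least 2-fold each time. Xcr1 was the most increased gene by the naming rule in each condition and H19 the most decreased. Among imprinted genes, Mest, a mesoderm-specific hydrolase, rose each time (22.9 to 64.2, 30.7 to 151 and 151 to 601 CPM), and Ascl2, H19, Igf2, Meg3, Nnat, Plagl1 and Rian fell each time. The call of Ascl2 in untreated cells was lost with effective-length offsets and without either of 2 libraries, and that of Plagl1 with doxycycline was lost with those offsets. Without chromosome 1 genes 1341 genes changed the same way in all 3 conditions (620 higher, 721 lower).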

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

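The trophectoderm explanations, the imprinting explanations and the Y chromosome explanation below were chosen only after the result was seen. The X homologue, autosome, base composition and part-of-chromosome checks were written down before their tests. The base composition and part-of-chromosome predictions already name chromosome 1, so they were written with its shift known.

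A test of the difference between the lines showed another response to doxycycline in KO than in WT for 3425 genes. It also passed for the pluripotency (adjusted p = 7.7e-14), trophectoderm (0.0052, and adjusted p = 0.24 with an estimated correlation), placental (2.6e-08), neural (2e-05), feeder fibroblast (0.00055), hypoxia and glycolysis (0.0027, and adjusted p = 0.57 with an estimated correlation) and imprinted lists (9.6e-06). Among named genes with a mean above the floor of 3 counts per library in all 4 groups, the log2 difference was 3.95 for Meis2, 2.84 for Vgf, 2.73 for Klhdc8a on chromosome 1, -4.45 for Klk7, -4.22 for Stra6l, -4.13 for Pou2f3, a POU factor of chemosensory cells, and -4.02 for Pth1r. It was 0.85 for Phf6, -1.80 for Pou5f1, -1.75 for Cdx2 and -0.85 for Hand1. Meis2 was already lower in untreated KO cells, so its difference includes that gap. The retinoic acid differences below use the same untreated libraries, so the recurrence of Meis2 and Pou2f3 there is not independent.

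For retinoic acid the same test passed for 3155 genes and for the pluripotency (6e-56), formative epiblast (1.1e-18), trophectoderm (0.0053, and adjusted p = 0.24 with an estimated correlation), primitive endoderm (5.5e-17), ribosome biogenesis (0.00055, and adjusted p = 0.12 with an estimated correlation) and p53 target lists (4.9e-15). The p53 targets were already higher in untreated KO cells, so their difference includes that gap. The log2 difference was 5.16 for Spink1, a protease inhibitor, 4.04 for Meis2, 3.86 for Apom, an apolipoprotein, -4.72 for Lefty2 on chromosome 1, -3.86 for Pou2f3, -3.54 for Wnt8a, a Wnt ligand whose call was lost without 1 untreated KO library, -2.16 for Nanog and -0.63 for Sox2.

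Trophectoderm genes lay lower in doxycycline-treated KO cells. Less complete removal of Oct4 would leave Pou5f1 higher in KO, but its change was -1.57. This is total Pou5f1 RNA, in which transgene reads are not told apart from any reads of the disrupted native alleles. More undifferentiated cells left in KO would raise the pluripotency list, but its median was -0.76. A smaller share of 1 trophectoderm-like cell type would lower its genes alike. Over the 16 members that rose at least 8-fold in WT the changes ran from -3.08 to -0.41, with an SD 10.6 times their median standard error. This argues against 1 common factor alone. That standard error covers only the spread between replicates, and trophectoderm genes already differed untreated, so a smaller share beside other changes is not excluded. An effect of the knockout on these genes remains possible, though with no rescue and no second KO line in the labels a difference between the lines may do the same.

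Imprinted genes differed between the lines in all 3 conditions. A switch of imprint that silences H19 could raise its partner Igf2, and likewise Dlk1 beside Meg3. The 6 changes of Igf2 and Dlk1 had a median of -0.6 (-2.14 to 0.05). Gene totals do not separate the parental alleles, and Igf2 also changed strongly with treatment, so these values cannot decide on such a switch. The same 8 imprinted genes passed in the same direction each time (1 higher, 7 lower), which could come from the knockout or from imprints that differed between the lines beforehand, and the data cannot tell these apart. They are not 8 separate loci, since Igf2 is the partner of H19. Meg3 and Rian also lie close together on chromosome 12 (starts at 109541001 and 109603940).

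Chromosome 1 genes were lower and Y genes higher in KO. The largest autosomal shift kept in all 3 conditions was 0.47, on chromosome 1, which fits a gained or lost autosome in some cells of either line, though RNA alone cannot prove it and no biological explanation was tested. Matching on GC content and length left the chromosome 1 median at or below -0.49, and the highest of its bins lay at -0.37, so neither base composition nor a part of the chromosome would account for it. Reads of X homologues given to Y genes would lower Ddx3x, Eif2s3x and Kdm6a. Their 9 changes had a median of -0.03 (-0.62 to 0.02), but that test could not tell. Ddx3y went from 21.7 to 59.3 CPM untreated while Ddx3x stood at 749.3 CPM in WT. Moved reads would barely lower Ddx3x, and the explanation is left open. Ddx3y, Eif2s3y and Uty differed from each other by at most 2.0 standard errors, as a different share of cells with a Y chromosome would give. The remaining Y gene tested was not part of this check. With doxycycline the 4 Y genes had a mean of 0.62 against a median of 1.17, so a shift common to all 4 is not shown.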

How the results depend on the processing

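The fits without chromosome 1 genes and with crossed pairs were chosen only after the result was seen. No call of a named gene or list changed direction under any setting tried, but the majority of some counts did. With upper-quartile factors KO against WT with doxycycline gave 4167 higher and 2706 lower genes (3197 and 3419 with TMM), and the doxycycline response difference 2161 and 1331 (1630 and 1795). With DESeq2 the retinoic acid response difference gave 870 and 846 (1308 and 1847). Untreated KO against WT (2713 and 2656) gave 1632 and 1977 with effective-length offsets and 2357 and 2753 with no filter, and with retinoic acid (3357 and 3578) it gave 3601 and 3343 with DESeq2 size factors. With DESeq2 the genes differing between KO and WT numbered 3430 untreated (3406 of them shared with edgeR's 5369) and 4265 with retinoic acid (4241 shared with 6935), and the response differed for 1981 (doxycycline) and 1716 (retinoic acid) genes against 3425 and 3155. With effective-length offsets these differences numbered 1988 and 1762. Genes changed in all 3 conditions numbered 1108 with effective-length offsets and 1174 with DESeq2 against 1772; the cause was not tested. Of the gene list tests 51 passed with an estimated correlation and 147 with fry, against 84, and the trophectoderm list's difference in the doxycycline response was lost with the former (adjusted p = 0.24). Upper-quartile factors moved the all-gene median of the WT doxycycline response from 0 to -0.113.

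The labels give the groups the same replicate numbers, but same-numbered libraries did not deviate together (correlations from -0.11 to 0.08 over 15 pairs of groups). With the replicate number as a block, 5214, 6472 and 6805 genes differed between KO and WT untreated, with doxycycline and with retinoic acid. The treatment responses held 11168, 11065, 13128 and 13414 genes, the response differences 3316 and 3009, all 3 conditions 1732, and the list tests 86; the trophectoderm list gave 9.2e-32 with doxycycline and 0.0056 for the response. The crossed pairing gave 7226 genes for doxycycline. Leaving out each library gave 3699 to 3952 genes untreated, 5395 to 5912 with doxycycline and 4989 to 5563 with retinoic acid for KO against WT, and 1473 to 1763 in all 3 conditions; a lone library was assumed to vary like the other groups. Without chromosome 1 genes the response differences numbered 3184 and 2973.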

Other observations

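The checks of other segments were chosen only after the result was seen. The scan covered 209 bins of 10 Mb on the other autosomes and chromosome X, and none on chromosome 1. Bins with medians past 0.3 in all 3 conditions lay on chromosome 8 from 60 to 70 Mb (-0.35, -0.37 and -0.34 over 44 genes) and 70 to 80 Mb (-0.34, -0.44 and -0.44 over 120 genes). The others lay on chromosome X from 90 to 100 Mb (-0.70, -0.52 and -0.55 over 35 genes) and 100 to 110 Mb (-0.65, -0.53 and -0.64 over 65 genes).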
